A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

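Total RNA from 12 samples of Synechocystis sp. PCC 6803 was hybridised to 1-colour arrays of 62334 spots. Per the labels' protocols, cells grew at 30 °C under 130 µmol photons m-2 s-1, RNA was prepared with hot phenol, and aliquots of 2 µg were labelled with Cy3 directly, without cDNA synthesis. Per the series' design text, samples were biological replicates, and the WT raw data were shared with another mutant's experiment. Groups were taken from the titles, which call the mutant DisA, whereas its source and genotype labels name dacA. The name dacA is used here. The treatment labels and the treatment protocol disagree on the carbon level at each hour, and the carbon level was not used.

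The intensity values are those deposited by the authors as written by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity is background-subtracted and detrended within the array, per the file headers, with low values set to a floor of each array, and is not normalized between arrays. The authors also deposited a table of log2 values. These follow the rank of each array's own median spot signal, without background subtraction. Their column medians were 10.07 and 10.02 in the mutant at 0 h, 10.06 and 10.32 at 3 h and 10.09 and 9.80 at 24 h, and in WT 9.73 and 9.70, 10.16 and 10.08, and 10.07 and 9.76. limma is named in the submitters' processing notes with no version, and how these values were centred is not given in the sources used here.

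The log2 processed intensity minus the 75th percentile of each array was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 6 groups with 1 shared spread and 6 residual degrees of freedom. Control spots and 20 outlier spots were left out. A probe was tested if it was well above background on both arrays of at least 1 group, which left out 25625 probes. Each probe had 1 spot. Benjamini-Hochberg adjustment was applied within each of 10 comparisons, and changed means an adjusted p under 0.05. Where a probe was not well above background on any array of a group, a fold is given as a lower limit: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Group medians with dim probes at their lower limit set each array of the dimmer group that was not well above background in this way, and take 0 where no limit could be set. Groups of CRISPR probes were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, adjusted over 7 groups. Set medians per array were compared with an exact permutation test.

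On simulated data with 200 of 35390 probes changed, the test of the genotypes at 3 h recovered 28% of log2 changes of 1 and 91% of log2 changes of 2, with 2 wrong among 121 calls. The averaged test recovered 83% and 100%, with 11 wrong among 194. In the data 18.7% of probes changed between the genotypes at 3 h and 59.2% in the average, and the adjusted threshold depends on that share. No slide effect or floor was simulated. The rates therefore hold for the simulated setting and not for these comparisons.

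Slides were taken from the scanner files and numbered 1 to 3, with 4 arrays of this series on each. WT at 0 h and 24 h lay on slide 1, the mutant at 0 h and 24 h on slide 2, and both genotypes at 3 h on slide 3, scanned on a second day. With slide as a block, the comparisons within a slide keep their values by construction and the others cannot be estimated.

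Gene lists had been fixed for 290 genes in 27 lists, but none of their locus tags occurs among the probe names or in the reference gene table of assembly ASM28445v1, and 0 probe names matched that table. The lists, the dacA probes themselves and a prediction about carbon uptake genes were therefore not analysed here. The rule for named items, written before the data were examined, ranked the 7 largest rises and the 7 largest falls of protein-coding genes past the threshold without overlap of the groups. Its other parts, on dacA and its neighbours, non-coding features and list members, need gene names and were not applied. The rest was applied to all probes well above background on all arrays of the groups compared, and at most 2 unnamed probes per direction are given. The alternatives tried were normexp background correction with an offset of 50 on the median spot signal, quantile normalization, median centring, the authors' values, other filters on dim probes, trend and robust variance, array weights, only the arrays compared, the replicate number as a block, a log2 threshold of 1, and leaving out each array. The mean spot signal was not used here.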

Results

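Transcript levels were measured in Synechocystis sp. PCC 6803, a unicellular freshwater cyanobacterium, in the wild type (WT) and in a ΔdacA mutant that lacks the diadenylate cyclase, the enzyme that makes the signalling nucleotide c-di-AMP. Cultures were sampled at 0, 3 and 24 h around a change in carbon supply between air enriched to 5% CO2 and ambient air with 0.04% CO2. The 12 arrays form 6 groups of genotype and hour, with 2 biological replicates in each. The treatment labels place 0 h in low carbon and the later hours in high carbon, whereas the treatment protocol describes a shift to low carbon. Groups are therefore named here by genotype and hour, and no direction is tied to a carbon level. The number of arrays limits the precision of every value, since each group rests on 2 of them.

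Between 24109 and 33358 of the 61015 probes were well above background on an array, which is 39.5% to 54.7%. A total of 35390 probes entered the tests and 19708 of these were well above background on every array. Across probes, arrays of one group correlated with r between 0.980 and 0.987, and arrays of different groups with r between 0.771 and 0.966. The median absolute log2 difference between replicates ranged from 0.128 in the mutant at 3 h to 0.243 in the mutant at 0 h. The probe identifiers of 60866 probes are not paired with genes in the files used here, so the largest changes are given by probe. The 149 probes that carry a name belong to the 3 CRISPR arrays, repeat and spacer loci whose RNAs guide defence against foreign DNA, and to the leaders that precede the CRISPR1 and CRISPR2 arrays. The CRISPR and leader groups, and the division of CRISPR1 after probe 14 and after probe 47, were chosen after their values were seen, as were the CRISPR and leader probes given as examples. Whether probe numbers follow the order of the spacers is not given in the sources used here.

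**Figure D1:**
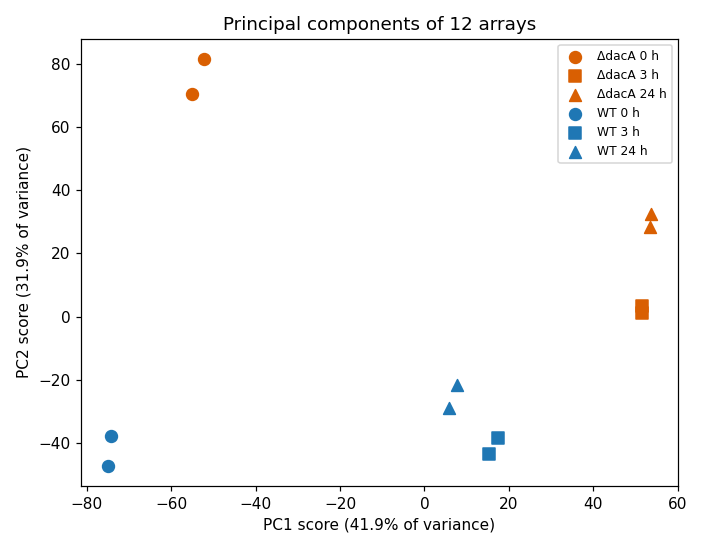
First and second principal component scores of the 12 arrays, computed over 19708 probes well above background on every array; each point is 1 array, with colour for genotype and shape for hour. The first component holds 41.9% of the variance and sets both 0 h groups (scores of -74.95 to -52.30) apart from the later hours, and the second holds 31.9% and sets the genotypes apart.

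The comparison of the mutant with WT asks which transcripts depend on dacA. In CRISPR1, most of probes 15 to 47 were near the floor of the arrays in WT and bright in the mutant. All 30 of the tested probes of this group were higher in the mutant at 0 h, at 3 h and at 24 h, with median log2 differences of at least 3.80, 4.35 and 5.58 when WT signals not well above background are set to their limit. Most of the 30 entered the tests only through their signal in the mutant, which favours this direction, so the count is no separate support. R_CRISPR1-23, R_CRISPR1-43 and R_CRISPR1-45 were dim in both genotypes and were not tested. Only R_CRISPR1-21 and R_CRISPR1-35 were well above background on all arrays, and both were higher at each hour. R_CRISPR1-18 had a scaled log2 signal of -4.06 ± 0.21 (SD, n = 2) in WT and 4.23 ± 0.30 in the mutant at 0 h. This probe was not well above background on any WT array, and its level in the mutant was at least 62.1-fold higher at 0 h and at least 84-fold higher at 3 h. Such lower limits could be set for 23, 24 and 27 probes of the group at 0, 3 and 24 h, with medians of 18-fold, 25-fold and 55-fold. R_CRISPR1-21 was well above background on all arrays and was at 0.22 ± 0.42 in WT and 2.27 ± 0.18 in the mutant at 0 h (n = 2 each; limma, adjusted p = 2.62e-05).

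Averaged over the arrays, the median of CRISPR1 probes 15 to 47 was 2.61 ± 0.82 (SD, n = 6) in the mutant. In WT, where 2 to 7 of the 33 probes were well above background on an array, it lay at the floor. The mutant was higher (two-sided exact permutation test within hours, p = 0.00926, the smallest that 216 relabelings can give; 0.013 after Benjamini-Hochberg adjustment over 7 groups). This group was cut where the genotypes part, after the values were seen, so this p is no independent test of the difference. The relabelings also exchange arrays across slides at 0 h and 24 h, where slide and genotype cannot be told apart. Lower limits over all hours could be set for 23 probes, with a median of 32.5-fold. The difference was present at 3 h, where both genotypes lay on the same slide. With limma's camera and an estimated correlation, adjusted p = 0.0663 for the average over the hours, which did not pass, and 0.123 at 0 h, 0.0206 at 3 h and 0.0321 at 24 h. The preset correlation gave an adjusted p of 1.25e-21 at 0 h. These camera values too are for a group cut by the difference that they test. Under 8 scalings and background settings the median stayed above 0, with 1.93, 2.38 and 3.52 as its lowest at 0 h, 3 h and 24 h.

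CRISPR1 probes 1 to 14 were also higher in the mutant, by less. At 0 h 12 of 14 were higher, at 3 h 9 and at 24 h 14, with median log2 differences of 0.87, 0.69 and 1.36 when the 1 probe dim in WT is set to its limit. Over 8 scalings and background settings the median at 0 h ranged from 0.35 to 1.34. R_CRISPR1-1 was at 6.39 ± 0.04 in WT and 7.29 ± 0.30 in the mutant at 0 h (n = 2 each; limma, adjusted p = 0.00165). With an estimated correlation, adjusted p = 0.352, 0.171 and 0.109 at the 3 times. The count at 3 h was 3 with median centring, 5 without the filter on dim probes, 4 with only the arrays compared and 2 without mutant replicate 1, mutant replicate 2 or WT replicate 1 at 3 h, and 4 without WT replicate 2. At 0 h it was 7 without mutant replicate 2. Of CRISPR1 probes 48 and 49, 1 was lower in the mutant at each hour. R_CRISPR1-49 was well above background on 6 of 6 WT arrays and 2 of 6 mutant arrays, and at 3 h its level was at least 2.91-fold higher in WT. R_CRISPR1-48 did not pass at any hour. Neither was well above background in the mutant at 0 h. With both at their lower limit the median of the pair was -0.56 there, and it was 0.03 in the authors' values.

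All 4 probes of the CRISPR1 leader, the stretch upstream of the array that carries its promoter, were higher in the mutant at each hour, with median log2 differences of 0.81 (0.32 to 1.28 over the 8 settings), 1.22 and 2.22. R_LEADER1-1 reached 6.17 ± 0.13 in the mutant and 3.94 ± 0.04 in WT at 24 h (n = 2 each). The estimated correlation gave adjusted p = 0.352, 0.164 and 0.109 for the group, and at 0 h 2 of the 4 probes passed without mutant replicate 2 at 0 h. The exact permutation test over 6 arrays per genotype gave a difference of 1.29 (p = 0.00926), for a group chosen after its values were seen.

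CRISPR3 probes were lower in the mutant, 10 of the 21 tested at 0 h, 15 at 3 h and 18 at 24 h, and none was higher. On an array 18 to 22 of the 38 CRISPR3 probes were well above background in WT, against 8 to 10 in the mutant. Probes that entered the tests only through WT favour this direction, so these counts are no separate support. Over probes well above background on all arrays, 1, 5 and 5 were lower at 0 h, 3 h and 24 h. With dim probes at their lower limit, the median log2 differences were -0.24, -1.17 and -1.13. The medians without these limits ranged over the 8 settings from -0.90 to -0.10 at 0 h, from -1.61 to -0.76 at 3 h and from -2.33 to -0.58 at 24 h. R_CRISPR3-2 was at 5.43 ± 0.11 in WT and -2.32 ± 0.85 in the mutant at 3 h (n = 2 each), where its level in WT was at least 151-fold higher. R_CRISPR3-7 and R_CRISPR3-14 showed the same order at 3 h, with levels in WT at least 7.23-fold and 14.2-fold higher. R_CRISPR3-9 did not pass, at 6.17 ± 0.40 in WT and 5.30 ± 0.06 in the mutant at 3 h. With an estimated correlation, adjusted p = 0.352, 0.0464 and 0.109 at the 3 times.

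Of 24 CRISPR2 probes tested, 14 were higher in the mutant at 0 h, 2 at 3 h and 1 at 24 h, where 8 were lower. The estimated correlation gave adjusted p = 0.352, 0.498 and 0.786. The median at 24 h was -0.06, and 0.13 with median centring. Neither of the 2 tested LEADER2 probes passed at any hour. The exact permutation test over 6 arrays per genotype gave a difference of 0.16 for LEADER2 (p = 0.454).

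**Figure D2:**
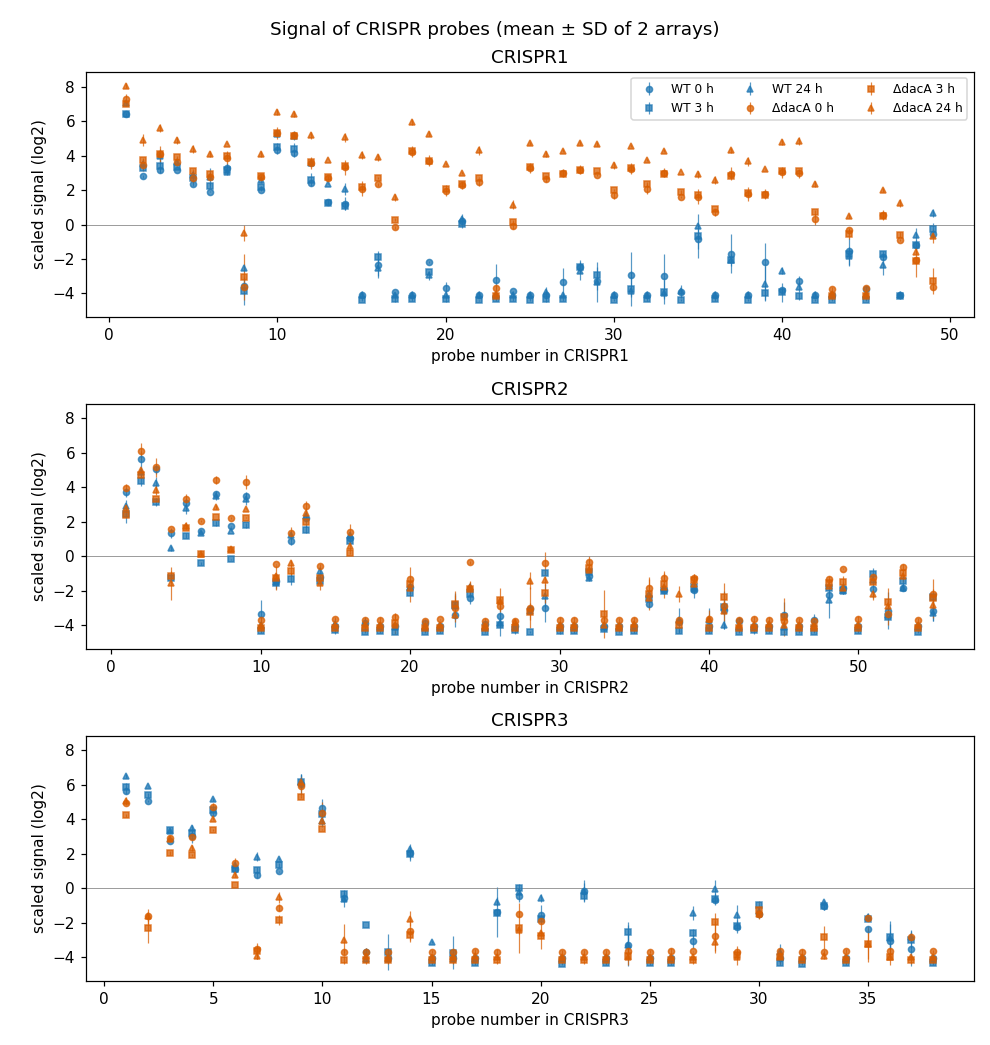
Scaled log2 signal of each CRISPR probe against its number, with points for the mean and bars for the SD of 2 arrays; blue is WT, orange is ΔdacA, and the shape gives the hour. In CRISPR1 the genotypes part at probe 15, where WT stayed at -4.06 and the mutant at 2.08 at 0 h, and in CRISPR3 single probes such as number 2 were dim in the mutant only.

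Over all probes, the genotypes differed most at 0 h. At 0 h 9375 probes were higher and 10888 lower in the mutant, at 3 h 3084 and 3550, and at 24 h 5500 and 7110. In the authors' values 16029, 2616 and 4810 probes changed at 0 h, 3 h and 24 h. The median absolute log2 difference over probes detected on every array was 0.540 at 0 h, 0.292 at 3 h and 0.360 at 24 h. Averaged over the hours, 9543 probes were higher and 11415 lower, with SYN-CR-76-44680 higher by 5.87 and SYN-CR-76-13315 differing by -3.23. At 0 h SYN-CR-76-53562 was at -1.51 ± 0.08 in WT and 8.52 ± 0.27 in the mutant (n = 2 each), a log2 difference of 10.03, while SYN-CR-76-9985 was lower in the mutant by a log2 difference of -4.98. At 3 h SYN-CR-76-44680 was higher in the mutant by 6.56 and SYN-CR-76-13315 differed by -3.41. At 24 h SYN-CR-76-38104 was higher by 6.03 and SYN-CR-76-56665 differed by -3.64. Without WT replicate 2, mutant replicate 2 or WT replicate 1 at 3 h, the genotypes differed at 3 h for 3090, 3482 and 3966 probes. Without mutant replicate 2, WT replicate 2 or mutant replicate 1 at 24 h, they differed at 24 h for 7905, 7989 and 8220. Only the 3 h groups shared a slide. At 0 h and 24 h all WT arrays lay on slide 1 and all mutant arrays on slide 2, so that slide and genotype cannot be told apart there. On slide 1 between 18.9% and 47.7% of the E1A control spots were well above background, against 55.1% to 62.6% on slides 2 and 3. The share of higher probes among those changed depended on the scaling and on the filter on dim probes. At 0 h it was 46.3%, 62.0% over probes well above background on all arrays, and 69.0% with median centring, 35.3% with the 75th percentile of probes detected on all arrays and 83.8% in the authors' values. At 3 h it was 46.5%, and 63.0% in the authors' values. At 24 h it was 43.6%, and 60.0% with median centring. For the average it was 45.5%, 56.7% over probes well above background on all arrays, and 63.4% with median centring and 71.6% in the authors' values.

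The differences between the genotypes at separate hours were correlated across probes, which are not independent replicates. The correlation was r = 0.506 between 0 h and 3 h, 0.457 between 0 h and 24 h and 0.631 between 3 h and 24 h, over 19708 probes. At 0 h and 24 h the difference was slide 2 against slide 1. A slide effect would enter both and cannot be told apart from genotype in that correlation. At 3 h and 24 h 1882 probes were higher and 2245 lower in both, against 479 and 713 for independent lists, and 145 went opposite ways.

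**Figure D3:**
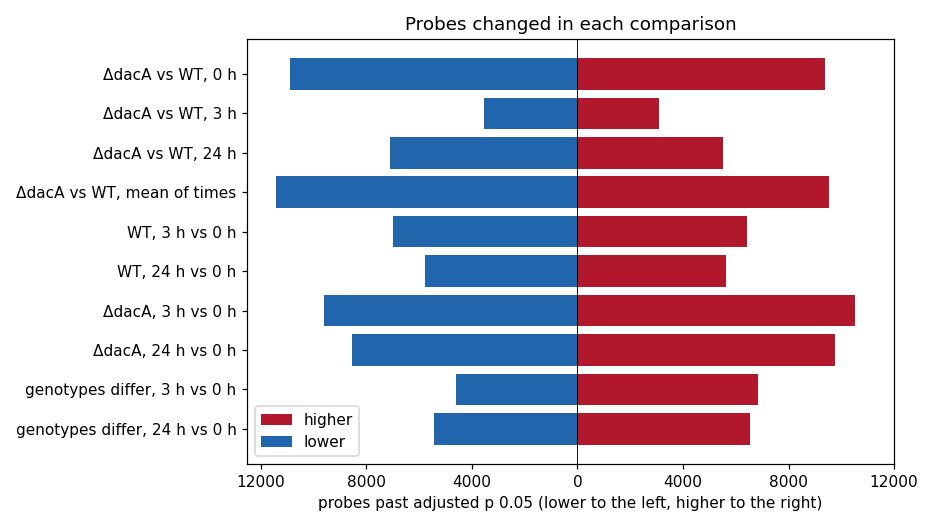
Number of probes past the adjusted p threshold in each of the 10 comparisons, with bars to the right for higher and to the left for lower probes. The mutant at 3 h against 0 h gave 10533 higher and 9603 lower probes, and the genotypes at 3 h gave 3084 and 3550.

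The comparison of hours asks how each genotype responded to the change in carbon supply. None of the groups was a culture kept without that change to 3 h or 24 h. Time in culture and carbon supply therefore cannot be told apart, and at 3 h against 0 h neither can slide. In WT, 10 of 24 CRISPR2 probes were lower at 3 h than at 0 h and 2 were higher, and both tested LEADER2 probes were lower, 1 of them without WT replicate 1 at 0 h or without either WT replicate at 3 h. R_CRISPR2-3 went from 5.04 ± 0.24 to 3.16 ± 0.24 (n = 2 each). The median CRISPR2 change was -0.46, and 0.31 in the authors' values, where all probes were shifted up by a median of 0.41. With an estimated correlation, adjusted p = 0.846. At 24 h 10 of 14 probes of CRISPR1 1 to 14 were higher in WT than at 0 h, with a median change of 0.82 and an adjusted p = 0.516 with an estimated correlation. This count was 5 with median centring, 3 without WT replicate 1 at 0 h, 6 without replicate 2 at 0 h and 4 without replicate 1 at 24 h. At 24 h 3 of 4 LEADER1 probes were lower, with a median change of -0.84 (-0.90 to -0.38 over the 8 settings). Of 21 CRISPR3 probes 6 were higher, with a median change of 0.59 (0.19 to 0.70; adjusted p = 0.516 for both groups with an estimated correlation).

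Over all probes in WT, 6411 rose and 6969 fell at 3 h, and 5639 rose and 5772 fell at 24 h. SYN-CR-76-53562 rose by 9.96 at 3 h and SYN-CR-76-13558 changed by -5.23. At 24 h SYN-CR-76-53562 stood 10.07 above its 0 h level and SYN-CR-76-19479 had changed by -5.60. The 24 h and 0 h arrays of WT shared slide 1, whereas the 3 h arrays lay on slide 3, which was scanned on another day. In WT at 3 h 47.9% of changed probes were higher, and 61.4% with the 75th percentile of probes detected on all arrays and 92.1% in the authors' values. At 24 h it was 49.4%, and 76.5% in the authors' values.

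In the mutant, 17 of 24 CRISPR2 probes were lower at 3 h than at 0 h and 15 at 24 h, and both tested LEADER2 probes were lower at each hour, with 1 at 3 h without mutant replicate 2 at 0 h. R_CRISPR2-9 went from 4.31 ± 0.43 at 0 h to 2.25 ± 0.03 at 3 h (n = 2 each). The median CRISPR2 change was -1.31 at 3 h and -1.04 at 24 h, with adjusted p = 0.781 and 0.351 with an estimated correlation. Over the 8 settings it ranged from -1.82 to -0.22 at 3 h and from -1.37 to -0.31 at 24 h. In CRISPR3 9 of 21 probes were lower and 1 higher at 3 h, with a median change of -0.67, and 4 were lower and 1 higher at 24 h, with -0.29. These medians were 0 with one floor for all arrays, and the estimated correlation gave adjusted p = 0.781 and 0.631. At 24 h 2 of 4 LEADER1 probes were higher, with a median change of 0.58 (0.25 to 0.86 over the 8 settings; adjusted p = 0.473 with an estimated correlation). At 24 h all 14 probes of CRISPR1 1 to 14 and 26 of 30 of probes 15 to 47 were higher than at 0 h, with median changes of 1.34 and 1.57 and an adjusted p = 0.351 for both with an estimated correlation.

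Over all probes in the mutant, 10533 rose and 9603 fell at 3 h, and 9778 rose and 8524 fell at 24 h. SYN-CR-76-11742 rose by 4.72 and SYN-CR-76-42769 changed by -6.34 at 3 h. At 24 h SYN-CR-76-30042 had risen by 5.16 and SYN-CR-76-26002 had changed by -5.84. The mutant's 0 h and 24 h arrays shared slide 2 and its 3 h arrays lay on slide 3. At 3 h 52.3% of changed probes were higher, 33.9% over probes well above background on all arrays, and 28.8% with median centring, 71.3% with the 75th percentile of probes detected on all arrays and 78.8% in the authors' values. At 24 h it was 53.4%, 38.4% over probes well above background on all arrays, and 35.0%, 64.2% and 41.2% with these scalings and values.

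Changes at 3 h in WT and in the mutant were correlated across probes with r = 0.586, and those at 24 h with r = 0.487. Within a genotype the 3 h and 24 h changes share the 0 h arrays. Their correlation was 0.799 in WT and 0.879 in the mutant, against 0.508 and 0.497 in simulated arrays with no effect. The covariance was 0.451 in WT and 0.717 in the mutant, against 0.0215 and 0.0205. Part of the excess may come from the shared 0 h arrays, which were too few to divide. In WT 3835 probes were higher and 3951 lower at both hours, against 1022 and 1137 for independent lists, and in the mutant 8227 and 6889, against 2910 and 2313.

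The difference in response asks whether dacA alters the change over time. From 0 h to 24 h all 4 LEADER1 probes moved up more, or down less, in the mutant, with a median difference in log2 change of 1.42. R_LEADER1-1 went from 4.83 ± 0.11 to 3.94 ± 0.04 in WT and from 5.75 ± 0.31 to 6.17 ± 0.13 in the mutant (n = 2 each). In CRISPR2 11 of 24 probes moved down more in the mutant, with a median difference of -0.97 (-1.25 to -0.27 over the 8 settings). The estimated correlation gave adjusted p = 0.356 for both groups. The change from 0 h differed between the genotypes for 11454 probes at 3 h, of which 6842 moved up more, or down less, in the mutant and 4612 the reverse. At 24 h it differed for 11986 probes, 6539 and 5447. The 24 h comparison lies within slides, since each genotype's 0 h and 24 h arrays shared a slide, and the 3 h comparison does not. The share moving up more in the mutant was 59.7% at 3 h, 37.2% over probes well above background on all arrays, and 28.1% with median centring, 71.7% with the 75th percentile of probes detected on all arrays and 30.0% in the authors' values. At 24 h it was 54.6%, 38.4% over probes well above background on all arrays, and 38.2% with median centring and 17.0% in the authors' values.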

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

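The tests of explanations in this part were all chosen after the results were seen.

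Differences between the genotypes in their change over time were found with limma's interaction terms for 11454 probes at 3 h and 11986 at 24 h. SYN-CR-76-53562 stood out at both, with log2 differences of -9.79 and -9.15, and was at -1.51 ± 0.08 in WT at 0 h and between 8.46 and 9.44 in the other groups. At 3 h SYN-CR-76-26540 differed by -5.54, SYN-CR-76-37883 by 3.45 and SYN-CR-76-36845 by 3.09. At 24 h SYN-CR-76-538 differed by -6.12, SYN-CR-76-28732 by 3.66 and SYN-CR-76-5915 by 3.64.

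Among CRISPR probes the change to 3 h was higher in the mutant for 2 CRISPR1 probes of 15 to 47, R_CRISPR1-17 and R_CRISPR1-41, neither well above background on any WT array. The median difference over the 30 tested probes of this group was 0.47, and -0.05 with median centring. The change to 3 h was lower for 4 CRISPR2 and 7 CRISPR3 probes. The change to 24 h was higher in the mutant for 4 probes of CRISPR1 1 to 14, for 23 of CRISPR1 15 to 47 and for 4 LEADER1 probes, and lower for 11 CRISPR2 and 8 CRISPR3 probes. It was also higher for 1 probe, R_CRISPR1-49, of CRISPR1 48 and 49, and the median difference of this pair, 0.79, was -0.59 with one floor for all arrays. With an estimated correlation, adjusted p = 0.946 for each of these groups at 3 h. At 24 h it was 0.579 for CRISPR1 1 to 14, 0.356 for CRISPR1 15 to 47, LEADER1 and CRISPR2, 0.459 for CRISPR3 and 0.702 for CRISPR1 48 and 49. The WT signal of most probes of CRISPR1 15 to 47 lay near the floor at each hour.

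Control spots outside the comparisons also gave signal. E1A control spots were well above background in at least 55.1% on slides 2 and 3, and in 18.9% to 47.7% on slide 1, which held WT at 0 h and 24 h. ERCC control spots gave 12.6% to 16.9% and 3.33% to 12.9%.

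For CRISPR1 probes 15 to 47, most of them near the floor in WT and bright in the mutant, a slide or scan effect is argued against by a median log2 difference of at least 4.35 at 3 h within slide 3, with dim probes at their lower limit. Scaling is argued against by the smallest median over settings and hours, 1.93, and a single array with the wrong genotype label by 0 of 12 arrays on the other genotype's side. A CRISPR1 segment that differs between the lines in the DNA stays open as a hypothesis, as DNA was not measured. Some of the 30 tested probes gave signal in WT. Of these, 2, R_CRISPR1-21 and R_CRISPR1-35, were well above background on all WT arrays. R_CRISPR1-44 was so on 4 WT arrays, R_CRISPR1-46 on 3, R_CRISPR1-16 and R_CRISPR1-37 on 2 each and R_CRISPR1-39 on 1. Lowered RNA of the segment in WT cannot be told apart from a difference in the DNA, since only 2 probes have higher numbers, with a difference of -1.70 (mutant minus WT) and near the floor in the mutant at 0 h. An exchange of all genotype labels stays open too, as dacA itself was not analysed here.

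The genotypes differed most at 0 h. A fixed difference between slides 1 and 2 adds equally at 0 h and 24 h by design, and explanations of the gap between these hours were not tested. Scaling is argued against for the gap between 0 h and 3 h, where the smallest ratio of changed probes over settings was 2.36. For that gap, a slide effect at 0 h and genotype cannot be told apart, since 0 slides hold both genotypes at 0 h. A response of the mutant that depends on the growth before the shift stays open and untested.

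Averaged over the hours, 20958 probes differed between the genotypes. Of 100 divisions drawn from the 108 possible within the hours, 1 gave as many, the real one, and the highest other gave 14466. In 3 of the other divisions replicates stayed together, with 10470 to 14466 probes, and these are too few to exclude chance by themselves. The rest mixed replicates, with 14090 as their highest, and the median over all others was 0. Mixing replicates puts differences between groups into the spread, which lowers these counts by construction. The divisions therefore cannot exclude chance.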

How the results depend on the processing

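Alternatives added after the data were seen were the authors' values scaled to their 75th percentile, the 75th percentile of probes detected on all arrays, one floor for all arrays, crossed numbers, and all those for CRISPR and leader groups and for probes seen in 1 genotype. All 1004 recomputed values of the 40 unnamed probes and comparisons kept their direction and stayed past the threshold. These were the largest changes, picked past the threshold from the same arrays, so this does not speak for other probes. Of 487 recomputed counts, 429 were within 1.5 times the main count, as were 444 of 468 without 1 array. The scaling moved the median of all probes, for the mutant at 3 h against 0 h from -0.04 to -0.54 (log2) with median centring, so that all changes are relative to it. The median over the probes of a feature was not run, as each probe had 1 spot, nor were the gene list alternatives. The cause of the changes below was not tested, except that fewer probes pass a fold threshold or are tested when all arrays must detect them.

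The authors' values gave 2616 changed probes between genotypes at 3 h, 4810 at 24 h and 13294 for the average, 21881 in WT at 3 h, 10163 and 7820 in the mutant at 3 h and 24 h, and 3277 and 5784 for the differences between genotypes. CRISPR2 lower in the mutant at 3 h gave 10 probes, LEADER2 in WT at 3 h 1, also with quantile normalization, the 75th percentile of probes detected on all arrays and only the arrays compared. Array medians of CRISPR2, with 15 to 24 of 55 probes well above background, and of CRISPR3 in the mutant, with 8 to 10 of 38, lay near the floor, so that their differences below measure no effect. The array medians differed between genotypes by -0.22 for CRISPR1 48 and 49 and by -0.09 for CRISPR3. Scaled to their 75th percentile they gave 7 probes of CRISPR1 1 to 14 and 2 of LEADER1 at 0 h, and differences between genotypes of 0.14 for CRISPR2 and -0.05 for LEADER2. Median centring gave 3 probes of CRISPR1 1 to 14 at 3 h, 5 in WT at 24 h and 0.80 for CRISPR2, quantile normalization 1.03, normexp 0.35 and -0.02 for LEADER2, and one floor 0 for CRISPR2 and -0.03 for CRISPR3. CRISPR1 1 to 14 at 3 h gave 5 without the filter and 4 with only the arrays compared.

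Probes well above background on all arrays gave 11489, 7602 and 11777 between genotypes at 0 h, 24 h and on average, 7991 and 7318 in WT, 11998 and 10969 in the mutant, and 6397 and 7362 for the differences. CRISPR1 15 to 47 gave 2 at each hour and 2 in the mutant at 24 h, CRISPR3 1, 5 and 5, and CRISPR2 11 in the mutant at 3 h. A log2 change of at least 1 left 12341, 3294, 6789 and 6115 between genotypes, 7553 and 6377 in WT, 12232 and 11070 in the mutant, 4 and 3 probes of CRISPR1 1 to 14 at 0 h and 3 h, 3 in WT at 24 h and 0 of LEADER1 at 0 h.

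Without 1 array, a lone array being assumed to vary like the others, the genotypes differed for 3090 to 7245 probes at 3 h (3090 and 3966 without WT replicate 2 and 1, 3482 without mutant replicate 2) and 7905 to 13315 at 24 h (8220 and 7905 without mutant replicate 1 and 2, 7989 without WT replicate 2). CRISPR1 1 to 14 ranged from 7 to 12 at 0 h, 2 to 9 at 3 h and 3 to 11 in WT at 24 h, LEADER1 from 2 to 4 at 0 h, LEADER2 from 1 to 2 in both genotypes at 3 h, the CRISPR2 difference from 0.46 to 0.71, LEADER2 from -0.03 to 0.37, and probes seen in WT alone from 287 to 489.

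Replicate numbers were not taken to pair the samples, as 6 of 15 correlations of deviations were over 0.1. These 6, of 0.364 to 0.596, were those among WT at 0 h and 3 h and the mutant at 0 h and 24 h. The others lay between -0.483 and 0.0279, and WT at 24 h was negative with every other group. In the groups of the first kind replicate 1 had the lower scaled median over probes detected on every array. In the mutant at 3 h and WT at 24 h it had the higher. Shared replicates and a signal property of the arrays can therefore not be told apart here. With the number as a block the genotypes differed for 20433, 6795 and 12686 probes at 0, 3 and 24 h and 21093 on average, and 13497, 11503, 20324, 18455, 11506 and 12104 probes changed in WT at 3 h and 24 h, in the mutant at 3 h and 24 h, and for the differences at 3 h and 24 h. No count moved by over 1.5 times. Crossing the WT 24 h numbers gave 14499 probes between genotypes at 24 h and 13222 in WT at 24 h.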

Other observations

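The count of probes detected in a single genotype was chosen after the data were seen. A total of 284 probes were well above background on all 6 WT arrays and on no mutant array, 4 of them CRISPR3 probes and 280 of them unnamed. In the other direction there were 71 such probes, 23 of them CRISPR1 probes and 48 unnamed. The highest number in any other division of the arrays within the hours was 23, of 108 divisions. Most other divisions parted replicates, so that a counted probe had to be detected in 1 replicate and missed in its partner. That lowers their numbers by construction, and the divisions cannot exclude chance. At 0 h and 24 h the genotypes also lay on separate slides. The first count was 489 without mutant replicate 1 at 3 h. At 0 h 26036 and 24109 probes were well above background on the mutant arrays, against 32802 and 28105 in WT. At 24 h it was 29001 and 28425 against 30444 and 31607, and at 3 h 31703 and 30730 against 33358 and 31648. Whether this lower detection accounts for the larger count in WT was not tested. What these unnamed probes measure is not given in the sources used here.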
